A study of Danio rerio with 32 samples.

How the data were processed

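RNA was measured by sequencing in livers dissected from zebrafish larvae, wild-type (WT) or nrf2 knockout (KO), that were exposed to acetaminophen (APAP) or to dimethyl sulfoxide (DMSO) and collected at 12 h or 24 h. The 8 groups hold 4 libraries each, and every library came from 20 pooled livers. Per the labels, total RNA was isolated with TRIzol and a column kit. The labels give no APAP dose, larval age, library kit or sequencing batch, and they do not state which of the zebrafish Nrf2 copies was mutated. They name bcl2fastq, Trim Galore, HISAT2 and HTSeq as tools and GRCz11 as the genome build, without versions, and they state neither the annotation release nor the strand setting.

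The deposited table holds raw counts, whole numbers of reads per Ensembl gene as the authors counted them, in 1 column per library. It lists 32519 genes, of which 29200 have a symbol. Total counts per library were between 3971569 and 6298523. The lines of the counting program for reads without a gene were used only to describe the libraries. No pair of libraries in a group was a copy of the other, with a lowest chi-square per degree of freedom of 15.5.

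Genes with enough counts for the 8 groups were kept with filterByExpr, which left 11384 genes. Counts were scaled by the trimmed mean of M values (TMM), and a model with 1 mean per group was fitted to all 32 libraries in edgeR 4.0.16 under R 4.3.3. The fit had 24 residual and 16.7 prior degrees of freedom and a common biological coefficient of variation of 0.743. Quasi-likelihood F-tests, which are two-sided, gave 12 comparisons: APAP against DMSO in each genotype and time, KO against WT in each treatment and time, the difference between KO and WT in the APAP response at each time, and the difference between 24 h and 12 h in the APAP response of each genotype. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes carry a prior count of 0.125. Their standard errors (SE) are the absolute log2 fold change over the square root of its F statistic. Values per library are CPM (counts scaled to library size) after scaling, given as mean ± SD.

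The comparisons, tests, gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from the 4 added alternatives and the tests stated to be chosen later. Named genes had an adjusted p under 0.05, a mean log2 CPM of at least 3, a symbol that is not a placeholder, and groups without overlap. The 8 highest and 8 lowest log2 fold changes were named for APAP against DMSO and for KO against WT under DMSO, and 4 and 4 for KO against WT under APAP. For differences of responses, 5 and 5 (KO against WT) and 3 and 3 (24 h against 12 h) were named without the condition on overlap. Up to 4 members with the smallest p of each called list and 22 genes fixed by name were added. The symbols SRXN1 and il1b of that last set were not tested for lack of counts. Among the named genes, 3 are not reported here.

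The 28 lists cover Nrf2 targets, proteasome subunits, endoplasmic reticulum stress, heat shock and chaperones, the p53 pathway, the cell cycle, ribosome biogenesis, stress-induced transcription factors, hepatocyte plasma proteins, xenobiotic metabolism, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, amino acid catabolism, glucose metabolism, bile acids, acute phase and inflammation, autophagy, and markers of neutrophils, macrophages, red blood cells, endothelium, stellate and mesenchymal cells, biliary cells, pancreas, intestine, skeletal muscle and epidermis. Of 1057 listed symbols, 818 matched a symbol in the table directly and 148 after a copy suffix was removed, a matching rule made after the symbols were seen. Lists with at least 5 tested members, 27 in all, were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance and compares them with no other genes, were run beside it. List means per library are means of log2(CPM + 2).

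Single values of groups were compared by exact permutation tests over the 70 assignments of 8 libraries, two-sided, with a smallest possible p of 0.0286. A library was called outlying in its group of 4 by Dixon's test with a critical value of 0.829, unless the other 3 had no counts. A fold against a group without counts is a lower bound from a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with its 95% counting interval. These floors and intervals cover counting error only.

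The alternatives were DESeq2 1.42.0 with its Wald test, scaling by relative log expression, no filter on low counts, only the compared groups in the fit, the replicate number as a block, genes with a mean log2 CPM of at least 3 for the agreement of responses, both other list tests, and each library left out in turn. The alternatives added after seeing the data were a fit without the 3 libraries with fewest detected genes, robust edgeR, limma voom with sample quality weights, and the pancreas marker level as a covariate. Other splits of the samples, 35 for 4 against 4 libraries and 100 drawn for differences of responses, were counted. The procedure was tested on simulated data with the same 11384 genes. For APAP against DMSO in WT at 24 h it recovered 32% of 100 genes changed 4-fold and 63% of 100 genes changed 16-fold, and for the difference between KO and WT responses at 24 h 6% and 41%. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9. Gene positions in GRCz11 were not used here. Chromosomes for a single test came from RefSeq names of the assembly GRCz12tu.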

Results

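Gene-level RNA counts were collected from zebrafish larval livers in 8 groups of 4 libraries, made by crossing genotype (WT or KO), treatment (APAP or DMSO) and time (12 h or 24 h). APAP, or paracetamol, is an analgesic whose reactive metabolite injures hepatocytes at high dose. Nrf2 is a transcription factor that switches on antioxidant and detoxification genes. The series asks how acute liver injury by APAP changes gene expression in WT and KO livers at both times. Total counts per library ran from 3971569 in WT APAP 12 h replicate 2 to 6298523 in KO DMSO 12 h replicate 1, with a median of 5354800. Unless another measure is named, values below are log2 fold changes ± SE from the fit to all 32 libraries, with n = 4 per group. Their adjusted p are from edgeR over 11384 tested genes.

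The libraries differed in how many genes they detected. Genes with at least 1 count numbered 4129 in KO APAP 12 h replicate 2, 8815 in WT DMSO 12 h replicate 2 and 9703 in KO DMSO 12 h replicate 3, against a median of 12096 over all libraries and a highest value of 14683. Pancreas marker genes, which the liver sample can carry from the adjacent organ, took 1.59% to 17.5% of counts, and red blood cell markers took 0.0285% to 0.319%. At 24 h the red blood cell share was 0.0494% ± 0.0147 (SD, n = 4) under APAP and 0.204% ± 0.0804 under DMSO in WT, and 0.0414% ± 0.0161 and 0.144% ± 0.0658 in KO. The pancreas share in KO at 24 h was 4.14% ± 0.435 under APAP and 7.59% ± 2.06 under DMSO. Each of these 3 differences had an exact permutation p of 0.0286, and none passed after adjustment over 48 tests of library composition, where the smallest adjusted p was 0.457. The intestine share, not among these tests, was 0.356% ± 0.0865 under APAP and 0.861% ± 0.161 under DMSO in KO at 24 h, without overlap. Mitochondrial genes took 3.69% to 7.40% of counts and the top 20 genes 24.4% to 37.6%. Reads without an alignment were 11.8% to 21.0% of all reads per library, and reads assigned to genes 66.3% to 78.7%.

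**Figure D1:**
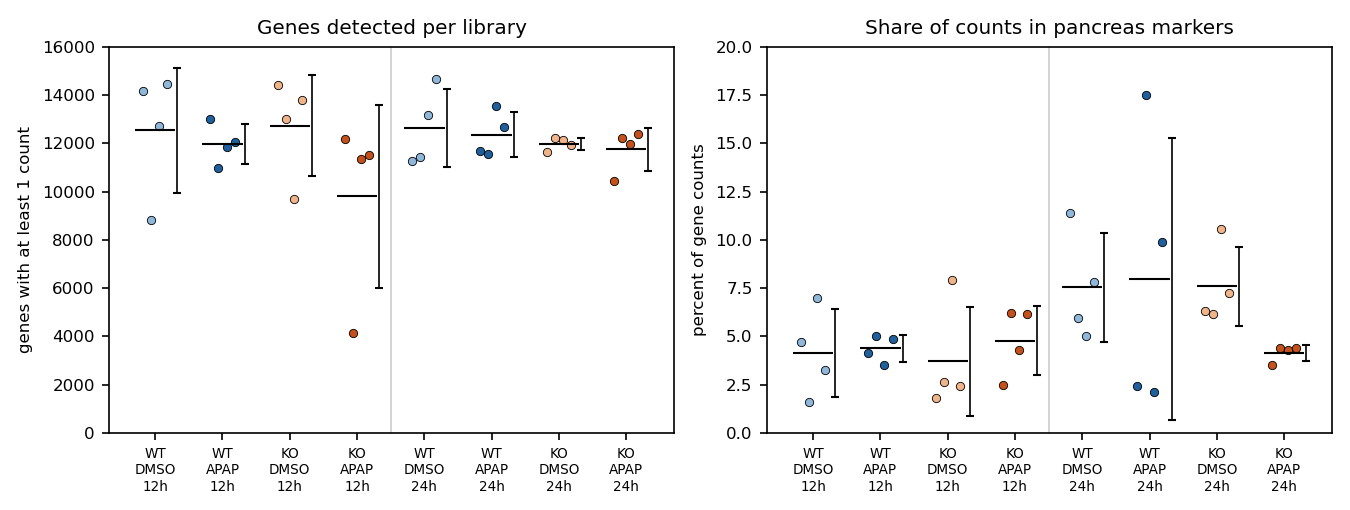
Genes with at least 1 count (left axis, number of genes) and percent of counts in pancreas marker genes (right panel) for each of the 32 libraries by group; points are libraries, the line is the mean and the bar the SD. KO APAP 12 h replicate 2 has 4129 detected genes against a median of 12096, and WT APAP 24 h replicate 2 has the highest pancreas share, 17.5%.

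The knocked-out gene was examined first. NFE2L2 (ENSDARG00000042824), the table's symbol for nfe2l2a, kept its transcript in KO livers: CPM at 12 h under DMSO was 40.4 ± 2.60 (SD, n = 4) in KO and 38.7 ± 12.3 in WT, and under APAP at 24 h it was 34.4 ± 4.80 and 54.2 ± 20.2. The log2 fold change of KO against WT was 0.06 and -0.22 under DMSO at 12 h and 24 h, and -0.72 and -0.66 under APAP, none of which passed, nor did any in another setting. The -0.72 became -0.37 without KO APAP 12 h replicate 2, which had 6.10 CPM against 36.7 to 41.2 in the other 3, and the -0.66 became -0.35 without WT APAP 24 h replicate 4, which had 83.9 CPM against 38.62 to 47.18. The second copy, nfe2l2b (ENSDARG00000089697), was low in every group, with mean CPM between 1.61 and 5.57. A mutant can keep its transcript, so these levels neither identify nor exclude the mutated copy.

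The first comparison asked which genes APAP changed in WT livers at 12 h. Of 29 Nrf2 target genes tested, 15 rose (adjusted over the list alone, 16 higher and 1 lower). The full list had a median log2 fold change of 2.08 (adjusted p = 4.19e-35, and adjusted p = 9.87e-07 with an estimated correlation). Those that rose included the peroxiredoxin gene prdx1 (ENSDARG00000058734) (4.80 ± 0.41), the glutathione reductase gene GSR (ENSDARG00000019236) (4.48 ± 0.42), the autophagy receptor gene SQSTM1 (ENSDARG00000075014) (3.39 ± 0.43) and KEAP1 (ENSDARG00000074634), the repressor of Nrf2 (2.80 ± 0.58). Levels of prdx1 went from 59.0 ± 8.10 CPM (SD, n = 4) under DMSO to 1639 ± 282 under APAP. Among stress-induced transcription factor genes (27 tested), 5 rose (adjusted over the list alone, 14). The median log2 fold change of the list was 1.17 (adjusted p = 3.16e-12, and adjusted p = 0.0190 with an estimated correlation). JUNB (ENSDARG00000074378), a subunit of AP-1, rose by 4.43 ± 0.81. The heat shock gene hsp70.3 (ENSDARG00000021924) had no counts in DMSO livers and was at least 64.5-fold higher under APAP, and HSP90AA1 (ENSDARG00000024746), a cytosolic chaperone, rose by 3.05 ± 0.64.

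Other genes that rose in WT at 12 h were ptgr1.2 (ENSDARG00000087017) (5.64 ± 0.92), named for prostaglandin reductase, the ferritin-like gene fthl31 (ENSDARG00000094210) (5.26 ± 0.67), the neuropeptide gene CARTPT (ENSDARG00000035852) (5.03 ± 0.75) and rtn4rl2b (ENSDARG00000037495) (ratio 263, 95% counting interval 46.6 to 10437). In the p53 pathway list (24 tested), 5 rose (adjusted over the list alone, 5). As a list, the tested members had a median log2 fold change of 0.19 (adjusted p = 0.00264, and adjusted p = 0.264 with an estimated correlation). BTG2 (ENSDARG00000020298) (3.98 ± 0.76), GADD45B (ENSDARG00000027744) (2.35 ± 0.46) and TP53INP1 (ENSDARG00000028017) (1.99 ± 0.44), genes of growth arrest and DNA damage, were among them. Of the autophagy genes (33 tested), 2 rose (adjusted over the list alone, 3). The list's median log2 fold change was 0.52 (adjusted p = 0.000333, and adjusted p = 0.206 with an estimated correlation). The genes that fell most included the glycogen-targeting subunit PPP1R3C (ENSDARG00000071005) (-3.67 ± 0.81), the sulfotransferase gene sult3st2 (ENSDARG00000093619) (-3.53 ± 0.63) and the carnitine transferase CPT1B (ENSDARG00000058285) (-3.24 ± 0.69). The largest adjusted p among the genes named for this comparison was 0.00690. Pancreas, intestine and skeletal muscle markers, no member of which passed, were higher as sets, with medians of 0.42, 0.47 and 0.45 (adjusted p = 0.0359, 0.0475 and 0.00549, and 0.882, 0.746 and 0.882 with an estimated correlation), and these 3 calls ended without the 3 libraries with fewest genes (0.558, 0.182 and 0.960). In all, 205 genes were called, 154 higher and 51 lower under APAP. The count was 408 with DESeq2 (210 higher and 198 lower), 414 without the 3 libraries with fewest genes and 389 with limma voom.

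The second comparison asked the same of WT livers at 24 h, where cell division genes stood out. Of 64 cell cycle genes tested, 18 rose (adjusted over the list alone, 31). Over all tested members the median log2 fold change was 2.38 (adjusted p = 4.42e-30, and adjusted p = 0.000674 with an estimated correlation). The mitotic kinases CDK1 (ENSDARG00000087554) (4.86 ± 0.68) and TTK (ENSDARG00000041361) (5.57 ± 0.86), the replication clamp gene PCNA (ENSDARG00000054155) (3.01 ± 0.37) and its partner pclaf (ENSDARG00000097691) (5.01 ± 0.61) rose. CDK1 was at 0.502 ± 0.621 CPM (SD, n = 4) under DMSO and 15.1 ± 7.46 under APAP. At 12 h it had been at 27.4 ± 5.55 and 16.1 ± 3.06. The list's mean log2(CPM + 2) in WT went from 3.08 at 12 h to 1.86 at 24 h under DMSO. Under APAP it went from 3.21 to 3.03, so these genes fell under DMSO rather than rose under APAP between the times. Nrf2 targets were higher at 24 h too: 9 rose and 1 fell (adjusted over the list alone, 16 and 2). For the list, the median log2 fold change was 1.12 (adjusted p = 8.80e-18, and adjusted p = 0.000294 with an estimated correlation). Of its members, prdx1 (4.81 ± 0.41) and GSR (3.79 ± 0.40) were among those that rose. Among 45 proteasome subunits, 6 rose (adjusted over the list alone, 11). Across the list's members the median log2 fold change was 0.76 (adjusted p = 7.42e-12, and adjusted p = 0.000884 with an estimated correlation).

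Of 48 hepatocyte plasma protein genes in WT at 24 h, 2 rose and 12 fell (adjusted over the list alone, 3 and 20). All members together had a median log2 fold change of -0.79 (adjusted p = 2.31e-11, and adjusted p = 0.189 with an estimated correlation). The list's mean log2(CPM + 2) in WT under APAP was 8.32 ± 0.346 (SD, n = 4) at 12 h and 8.21 ± 0.370 at 24 h. Under DMSO it was 8.34 ± 0.520 and 9.02 ± 0.229. The difference at 24 h thus went mostly with the higher DMSO level. The coagulation factor gene f9a (ENSDARG00000010097) (-3.61 ± 0.80), the fetuin gene ahsg1 (ENSDARG00000026764) (-3.46 ± 0.72) and the vitamin D binding protein gene GC (ENSDARG00000089310) (-1.69 ± 0.35) fell. Complement genes c4b (ENSDARG00000038424) (-3.47 ± 0.62) and c8b (ENSDARG00000039517) (-2.21 ± 0.47) fell as well, and in the acute phase and inflammation list (37 tested) 4 fell (adjusted over the list alone, 5). The members had a median log2 fold change of -0.49 (adjusted p = 0.00167, and adjusted p = 0.462 with an estimated correlation). CYP7A1 (ENSDARG00000069018), the rate-limiting enzyme of bile acid synthesis, fell (-5.11 ± 1.09), from 150 ± 56.6 CPM (SD, n = 4) to 4.43 ± 5.98. Of 31 fatty acid oxidation genes, 4 fell (adjusted over the list alone, 9). In the list as a whole, the median log2 fold change was -1.12 (adjusted p = 1.33e-11, and adjusted p = 0.0350 with an estimated correlation). Of 42 amino acid catabolism genes, 4 fell (adjusted over the list alone, 4). The full list had a median log2 fold change of -0.65 (adjusted p = 4.34e-06, and adjusted p = 0.252 with an estimated correlation). From 12 h to 24 h its mean log2(CPM + 2) in WT went from 5.55 ± 0.482 to 6.47 ± 0.170 under DMSO. Under APAP it went from 5.51 ± 0.236 to 5.82 ± 0.394. The list includes CBS (ENSDARG00000053500) (-3.13 ± 0.56), the first enzyme of transsulfuration. Of 67 xenobiotic metabolism genes, 6 rose and 8 fell (adjusted over the list alone, 7 and 15). The median log2 fold change of the list was -0.40 (adjusted p = 0.00167, and adjusted p = 0.194 with an estimated correlation). The respiratory chain gene cox7a1 (ENSDARG00000069464) fell (-3.76 ± 0.34).

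Of 9 red blood cell markers, 4 fell (adjusted over the list alone, 7). As a list, the tested members had a median log2 fold change of -2.14 (adjusted p = 6.78e-08, and adjusted p = 0.0350 with an estimated correlation). The alpha globin gene hbae3 (ENSDARG00000079305) fell (-2.46 ± 0.39); the share of counts in these markers was lower too, as given above. Skeletal muscle markers were higher as a set (29 tested, 1 rose (adjusted over the list alone, 5)). The list's median log2 fold change was 0.89 (adjusted p = 3.71e-05, and adjusted p = 0.489 with an estimated correlation). Pancreas markers, no member of which passed, were called lower with a median of 0.02 and a mean of -0.11 (adjusted p = 0.0193, and 0.720 with an estimated correlation). The call ended without WT APAP 24 h replicate 1 (0.574) or WT DMSO 24 h replicate 1 (0.262) and turned without WT APAP 24 h replicate 3 (0.981), in a group where the pancreas share ran from 2.13% to 17.5%. In all, 364 genes were called in WT at 24 h, 187 higher and 177 lower, and the largest adjusted p among those named was 0.00506. The split turned with DESeq2 (324 higher and 339 lower), limma voom (477 and 553) and 4 other settings. The count was 663 with DESeq2, 777 with only these groups in the fit, 916 without the 3 libraries with fewest genes and 1030 with limma voom. It was 229 without WT APAP 24 h replicate 2, 213 without replicate 3 of that group and 224 without WT DMSO 24 h replicate 2.

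In KO livers at 12 h, the third comparison, heat shock genes rose. Of 31 heat shock and chaperone genes, 6 rose (adjusted over the list alone, 11 higher and 1 lower). Over all tested members the median log2 fold change was 0.57 (adjusted p = 6.09e-08, and adjusted p = 0.0302 with an estimated correlation). Of its members, hsp70.3 had no counts under DMSO and was at least 314-fold higher under APAP, and hsp70l (ENSDARG00000055723) (6.80 ± 1.39) and HSP90AA1 (5.40 ± 0.71) rose. Of the stress-induced transcription factor genes, 10 rose (adjusted over the list alone, 13). For the list, the median log2 fold change was 1.60 (adjusted p = 5.02e-10, and adjusted p = 0.0302 with an estimated correlation). JUNB (5.11 ± 0.82) and FOSL1 (ENSDARG00000015355) (4.91 ± 0.80), both AP-1 subunits, were among them. Nrf2 targets rose in KO as well: 9 rose and 1 fell (adjusted over the list alone, 14 and 2). Across the list's members the median log2 fold change was 1.00 (adjusted p = 4.29e-09, and adjusted p = 0.0156 with an estimated correlation). prdx1 rose from 47.6 ± 23.9 CPM (SD, n = 4) to 344 ± 192 (2.85 ± 0.38), and NQO1 (ENSDARG00000010250), a quinone reductase gene, rose by 2.05 ± 0.40.

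CARTPT (9.04 ± 0.83) and the yolk precursor gene vtg7 (ENSDARG00000092419) (7.31 ± 0.90) had the highest fold changes in KO at 12 h beside hsp70.3, and CARTPT reached 152 ± 51.7 CPM (SD, n = 4) under APAP. Of 33 glucose metabolism genes, 5 rose and 1 fell (adjusted over the list alone, 7 and 1). All members together had a median log2 fold change of 0.24 (adjusted p = 0.000291, and adjusted p = 0.0999 with an estimated correlation). PFKFB3 (ENSDARG00000001953) (5.65 ± 1.02), a regulator of glycolysis, and PCK1 (ENSDARG00000013522) (3.46 ± 0.42), a gluconeogenic enzyme, were among them. Of the p53 pathway genes, 5 rose (adjusted over the list alone, 7). The members had a median log2 fold change of 0.69 (adjusted p = 6.19e-05, and adjusted p = 0.0601 with an estimated correlation). Fatty acid oxidation genes were lower: 1 rose and 7 fell (adjusted over the list alone, 1 and 13). In the list as a whole, the median log2 fold change was -1.29 (adjusted p = 2.62e-07, and adjusted p = 0.0896 with an estimated correlation). ECI1 (ENSDARG00000018002) (-2.13 ± 0.35) was among those that fell. Of 20 cholesterol synthesis genes, 2 rose and 4 fell (adjusted over the list alone, 2 and 9). The full list had a median log2 fold change of -1.70 (adjusted p = 0.00547, and adjusted p = 0.473 with an estimated correlation). Amino acid catabolism genes went both ways: 9 rose (adjusted over the list alone, 9 higher and 2 lower), with ARG2 (ENSDARG00000039269) (2.83 ± 0.48) higher; the list's median was -0.11, its mean 0.08, and the test with the preset correlation called it higher (adjusted p = 0.0167, and adjusted p = 0.596 with an estimated correlation), a call that ended without KO APAP 12 h replicate 3 (0.131) or KO DMSO 12 h replicate 2 (0.201). NIPAL4 (ENSDARG00000059365) was nearly absent under APAP (ratio 0.00234, 95% counting interval 5.91e-05 to 0.0131), and SPAM1 (ENSDARG00000004199) was lower (ratio 0.0113, 95% counting interval 0.00232 to 0.0332), as was the glucuronosyltransferase gene ugt5b3 (ENSDARG00000099276) (-5.41 ± 0.90).

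Pancreas and skeletal muscle markers, no member of which passed, were higher as sets in KO at 12 h, with medians of 0.81 and 0.42 (adjusted p = 1.66e-05 and 0.00768, and 0.486 and 0.688 with an estimated correlation). The muscle call ended without KO APAP 12 h replicate 2 (0.0545) or KO DMSO 12 h replicate 3 (0.0523). In all, 594 genes were called in KO at 12 h, 352 higher and 242 lower, against a median of -0.30 over all tested genes, and the largest adjusted p among those named was 0.00200. Which direction has more calls depends on the scaling, with 244 higher and 345 lower by relative log expression and 424 and 834 with DESeq2. The count was 1258 with DESeq2, 1004 with limma voom and 91 with only these groups in the fit, and it was 351 without KO DMSO 12 h replicate 1 and 356 without replicate 4. Without the 3 libraries with fewest genes, 2 of which are in these groups, the count was 595; the Nrf2 list then had a median of 0.39, adjusted p = 2.26e-05, and adjusted p = 0.0607 with an estimated correlation, so that the latter call ended.

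In KO livers at 24 h, the fourth comparison, proteasome genes rose together. Of the 45 subunits, 15 rose (adjusted over the list alone, 29). The median log2 fold change of the list was 1.23 (adjusted p = 1.83e-21, and adjusted p = 3.01e-05 with an estimated correlation). PSMD3 (ENSDARG00000018124) (1.92 ± 0.38), PSMB1 (ENSDARG00000009640) (1.74 ± 0.29) and PSMD8 (ENSDARG00000020454) (1.66 ± 0.34) were among them. Of the heat shock and chaperone genes, 6 rose (adjusted over the list alone, 8). As a list, the tested members had a median log2 fold change of 0.72 (adjusted p = 6.77e-06, and adjusted p = 0.0484 with an estimated correlation). HSP90AA1 rose by 3.77 ± 0.66, and hsp70.3 was at least 46.8-fold higher. Of the Nrf2 targets, 9 rose and 2 fell (adjusted over the list alone, 11 and 2). The list's median log2 fold change was 0.83 (adjusted p = 4.29e-05, and adjusted p = 0.0484 with an estimated correlation). Of its members, prdx1 (3.70 ± 0.40), the thioredoxin gene txnb (ENSDARG00000044125) (4.49 ± 0.53) and GSR (2.27 ± 0.39) rose. CARTPT was higher under APAP (ratio 872, 95% counting interval 156 to 34469), and vtg7 (9.46 ± 1.00) and the angiotensinogen gene agt (ENSDARG00000016412) (3.18 ± 0.29) rose. Of the cell cycle genes, 4 rose (adjusted over the list alone, 4). Over all tested members the median log2 fold change was 0.88 (adjusted p = 0.000281, and adjusted p = 0.261 with an estimated correlation). The list's mean log2(CPM + 2) in KO went from 3.10 at 12 h to 2.08 at 24 h under DMSO. Under APAP it went from 2.58 to 2.43.

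Of the fatty acid oxidation genes in KO at 24 h, 11 fell (adjusted over the list alone, 21). For the list, the median log2 fold change was -1.33 (adjusted p = 8.55e-14, and adjusted p = 0.0251 with an estimated correlation). The list includes DECR1 (ENSDARG00000003869) (-3.75 ± 0.68), EHHADH (ENSDARG00000070029) (-2.80 ± 0.49) and HADH (ENSDARG00000030765) (-1.72 ± 0.40), enzymes of the oxidation steps. Of the xenobiotic metabolism genes, 2 rose and 15 fell (adjusted over the list alone, 2 and 20). Across the list's members the median log2 fold change was -0.80 (adjusted p = 4.11e-08, and adjusted p = 0.0251 with an estimated correlation). The glutathione transferase gene GSTZ1 (ENSDARG00000027984) (-2.77 ± 0.39) and the cytochromes cyp2ad2 (ENSDARG00000021172) (-3.67 ± 0.46) and cyp2n13 (ENSDARG00000042953) (-3.38 ± 0.43) fell. Of 13 bile acid genes, 3 fell (adjusted over the list alone, 4). All members together had a median log2 fold change of -1.08 (adjusted p = 0.00446, and adjusted p = 0.0358 with an estimated correlation). CYP7A1 (-5.76 ± 1.15) and the bile salt export pump gene ABCB11 (ENSDARG00000070078) (-2.87 ± 0.60) fell. Of the plasma protein genes, 3 rose and 17 fell (adjusted over the list alone, 4 and 24). The members had a median log2 fold change of -1.09 (adjusted p = 9.38e-10, and adjusted p = 0.181 with an estimated correlation). Of its members, f9a (-4.51 ± 0.84), c8b (-3.66 ± 0.50) and GC (-2.61 ± 0.36) fell. In the acute phase list, 1 rose and 6 fell (adjusted over the list alone, 2 and 8). In the list as a whole, the median log2 fold change was -0.42 (adjusted p = 0.000562, and adjusted p = 0.261 with an estimated correlation). The complement gene bfb (ENSDARG00000005616) fell (-5.12 ± 0.85). Of the glucose metabolism genes, 7 rose and 2 fell (adjusted over the list alone, 8 and 4). The full list had a median log2 fold change of 0.56 (adjusted p = 0.00345, and adjusted p = 0.181 with an estimated correlation). The list includes ALDOC (ENSDARG00000019702) (2.68 ± 0.56).

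Of the red blood cell markers in KO at 24 h, 3 fell (adjusted over the list alone, 3). The median log2 fold change of the list was -1.41 (adjusted p = 0.000270, and adjusted p = 0.156 with an estimated correlation). Of 25 pancreas markers, 6 fell (adjusted over the list alone, 10). As a list, the tested members had a median log2 fold change of -1.06 (adjusted p = 4.11e-08, and adjusted p = 0.261 with an estimated correlation). The digestive phospholipase gene PLA2G1B (ENSDARG00000009153) was among them (-3.17 ± 0.59); the pancreas share of counts was lower as well, as given above. In all, 575 genes were called, 233 higher and 342 lower, with a largest adjusted p of 0.00517 among those named. The count was 894 with DESeq2, 1215 without the 3 libraries with fewest genes, 1436 with only these groups in the fit and 1633 with limma voom, and 373 without KO APAP 24 h replicate 1.

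**Figure D2:**
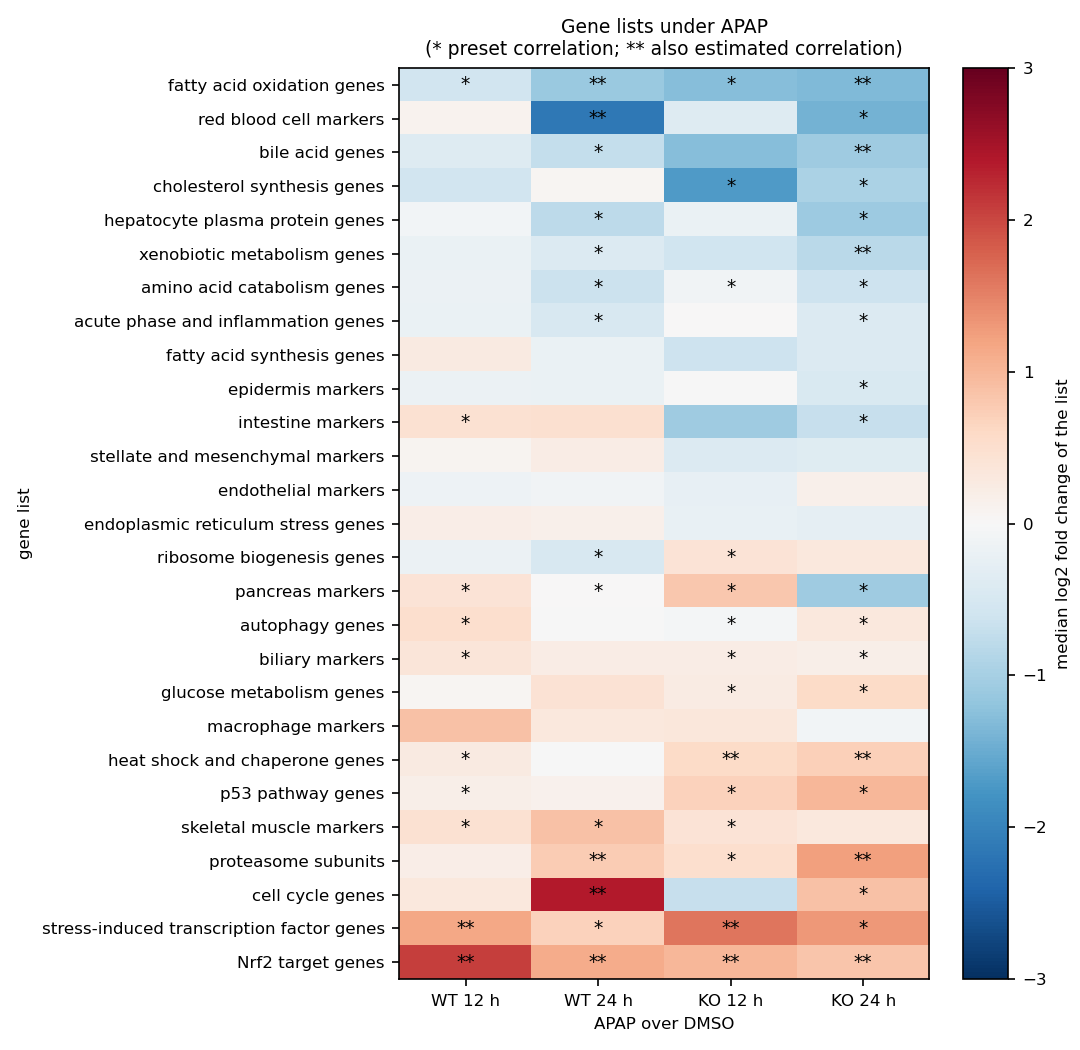
Median log2 fold change under APAP (colour) of each of 27 gene lists in WT and KO livers at 12 h and 24 h; 1 star marks a list called with the preset correlation and a second star a list called also with an estimated correlation. Nrf2 targets have medians of 2.08 and 1.12 in WT and 1.00 and 0.83 in KO, and cell cycle genes 2.38 in WT and 0.88 in KO at 24 h.

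The APAP responses of the groups were then compared across genes, which are not independent replicates. Log2 fold changes in KO and WT had a Pearson r of 0.355 and a Spearman rho of 0.355 at 12 h, and 0.437 and 0.447 at 24 h. At 12 h 106 genes rose in both genotypes, against 4.76 for independent calls, and 31 fell in both, against 1.08. At 24 h 84 rose in both, against 3.83, and 129 fell in both, against 5.32. Of the 661 genes called in either genotype at 12 h, 91.5% had the same sign in both, and of the 726 at 24 h, 96.0%. Between 24 h and 12 h the r was 0.346 in WT and 0.355 in KO. In the 4469 genes with a mean log2 CPM of at least 3 the 4 values were 0.599, 0.723, 0.614 and 0.620, in the same order.

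Genes that differ between the genotypes without APAP were sought in DMSO livers. At 12 h cyp2p9 (ENSDARG00000022631), a cytochrome P450 gene, was lower in KO (-4.75 ± 0.55), with 2.50 ± 1.68 CPM (SD, n = 4) against 67.1 ± 39, and so were the fatty acid transport gene SLC27A1 (ENSDARG00000104949) (-5.93 ± 1.01) and the granulin gene grna.2 (ENSDARG00000088641) (-6.94 ± 0.99). The transaminase gene AGXT2 (ENSDARG00000100709) (2.61 ± 0.43) and the respiratory complex gene ndufc1 (ENSDARG00000103101) (1.94 ± 0.34) were higher in KO, and the largest adjusted p of these 5 was 0.00240. In all, 28 genes were called, 16 higher and 12 lower in KO. For gene lists the smallest adjusted p was 0.137. The split turned to 3 higher and 10 lower with only these groups in the fit. The count was 104 with DESeq2, 146 with limma voom, 74 without the filter on low counts, 68 without the 3 libraries with fewest genes and 13 with only these groups in the fit. It was 16 and 12 without KO DMSO 12 h replicate 1 or 2, and 15, 14 and 16 without WT DMSO 12 h replicate 2, 3 or 4.

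At 24 h under DMSO cyp2p9 was again lower in KO (-3.40 ± 0.52) and AGXT2 higher (3.19 ± 0.44). The disulfide isomerase gene PDIA6 (ENSDARG00000009001) was higher (2.17 ± 0.39), while the thioredoxin reductase gene TXNRD3 (ENSDARG00000100374) (-1.54 ± 0.28) and QDPR (ENSDARG00000040190), which recycles tetrahydrobiopterin (-2.50 ± 0.43), were lower, with a largest adjusted p of 0.00345. Of the Nrf2 targets, 2 were lower in KO (adjusted over the list alone, 6 lower and 2 higher). The list's median log2 fold change was -0.53 (adjusted p = 0.00612, and adjusted p = 0.491 with an estimated correlation). Cell cycle genes were higher as a set, with a median log2 fold change of 0.52 (adjusted p = 0.00188, and adjusted p = 0.491 with an estimated correlation). In all, 32 genes were called, 15 higher and 17 lower. The split turned with limma voom (234 higher and 194 lower), with only these groups in the fit (227 and 181), without the 3 libraries with fewest genes (100 and 71) and with the pancreas covariate (18 and 17). The count was 113 with DESeq2, 428 with limma voom, 75 without the filter, 171 without the 3 libraries with fewest genes and 408 with only these groups in the fit. It was 18, 17 and 21 without KO DMSO 24 h replicate 1, 2 or 4, and 21, 13 and 20 without WT DMSO 24 h replicate 1, 2 or 3.

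Under APAP at 12 h, KO livers had less of several Nrf2 targets than WT livers. Of the 29 tested, 8 were lower in KO (adjusted over the list alone, 14 lower and 5 higher). Over all tested members the median log2 fold change was -0.91 (adjusted p = 0.000881, and adjusted p = 0.175 with an estimated correlation). Of its members, prdx1 (-2.25 ± 0.37), GSR (-1.92 ± 0.37) and PIR (ENSDARG00000056638) (-5.11 ± 0.93) were lower. The hypoxia and stress gene NDRG1 (ENSDARG00000032849) (4.18 ± 0.44), vtg7 (5.99 ± 0.85), CARTPT (4.05 ± 0.63) and ARG2 (2.34 ± 0.47) were higher in KO, and cyp2p9 was lower (-7.28 ± 0.66). Of the heat shock and chaperone genes, 5 were higher in KO (adjusted over the list alone, 6). For the list, the median log2 fold change was 0.53 (adjusted p = 2.36e-05, and adjusted p = 0.101 with an estimated correlation). In all, 254 genes were called, 146 higher and 108 lower in KO, with a median of -0.30 over all genes and a largest adjusted p of 0.00396 among those named. The majority again depends on the scaling, with 95 higher and 126 lower by relative log expression and 293 and 468 with DESeq2. The count was 761 with DESeq2 and 32 with only these groups in the fit, and 112, 128 and 101 without WT APAP 12 h replicate 1, 2 or 3. The Nrf2 list's call ended without KO APAP 12 h replicate 3 (adjusted p = 0.101), and without the 3 libraries with fewest genes the list had a median of -0.97, adjusted p = 1.41e-08, and adjusted p = 0.0227 with an estimated correlation.

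Under APAP at 24 h, Nrf2 targets were again lower in KO than in WT: 10 were lower in KO (adjusted over the list alone, 14 lower and 1 higher). Across the list's members the median log2 fold change was -1.21 (adjusted p = 1.02e-14, and adjusted p = 0.000941 with an estimated correlation). ptgr1.2 (-5.83 ± 0.94), the glutathione transferase genes gstt1b (ENSDARG00000017388) (-3.30 ± 0.41) and gstp1.2 (ENSDARG00000104068) (-2.57 ± 0.36), prdx1 (-2.87 ± 0.38) and GSR (-2.44 ± 0.38) were lower, and SLC27A1, without counts in KO, was at least 95.5-fold lower. Of the proteasome subunits, 3 were higher in KO (adjusted over the list alone, 12). All members together had a median log2 fold change of 0.56 (adjusted p = 1.51e-10, and adjusted p = 0.00202 with an estimated correlation). Of the heat shock and chaperone genes, 4 were higher in KO (adjusted over the list alone, 9). The members had a median log2 fold change of 0.69 (adjusted p = 1.72e-10, and adjusted p = 0.00711 with an estimated correlation). HSPA9 (ENSDARG00000003035) (2.01 ± 0.31), a mitochondrial chaperone, and HSPA8 (ENSDARG00000068992) (1.18 ± 0.25), a cytosolic chaperone, were among them. NDRG1 (3.68 ± 0.43), vtg7 (6.15 ± 0.84) and the stress transcription factor gene atf5b (ENSDARG00000077785) (3.98 ± 0.62) were higher in KO. Of the xenobiotic metabolism genes, 6 were lower in KO (adjusted over the list alone, 8). In the list as a whole, the median log2 fold change was -0.48 (adjusted p = 0.000470, and adjusted p = 0.203 with an estimated correlation). Cell cycle genes were lower as a set, with a median log2 fold change of -0.98 (adjusted p = 5.12e-08, and adjusted p = 0.172 with an estimated correlation). Ribosome biogenesis genes (58 tested) were higher as a set, with a median log2 fold change of 0.56 (adjusted p = 9.47e-06, and adjusted p = 0.339 with an estimated correlation). Intestine and skeletal muscle markers were lower as sets, with medians of -0.56 and -0.67 (adjusted p = 0.0244 and 0.000470, and 0.688 and 0.694 with an estimated correlation), and the intestine call ended without any 1 of 4 libraries (0.0533 to 0.266). In all, 136 genes were called, 65 higher and 71 lower, with a largest adjusted p of 0.00542 among those named. The split turned to 314 higher and 255 lower with limma voom and to 77 and 76 with the pancreas covariate. The count was 297 with DESeq2, 324 with only these groups in the fit, 443 without the 3 libraries with fewest genes and 569 with limma voom, and 76, 83 and 86 without KO APAP 24 h replicate 3, replicate 4 or WT APAP 24 h replicate 4.

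**Figure D3:**
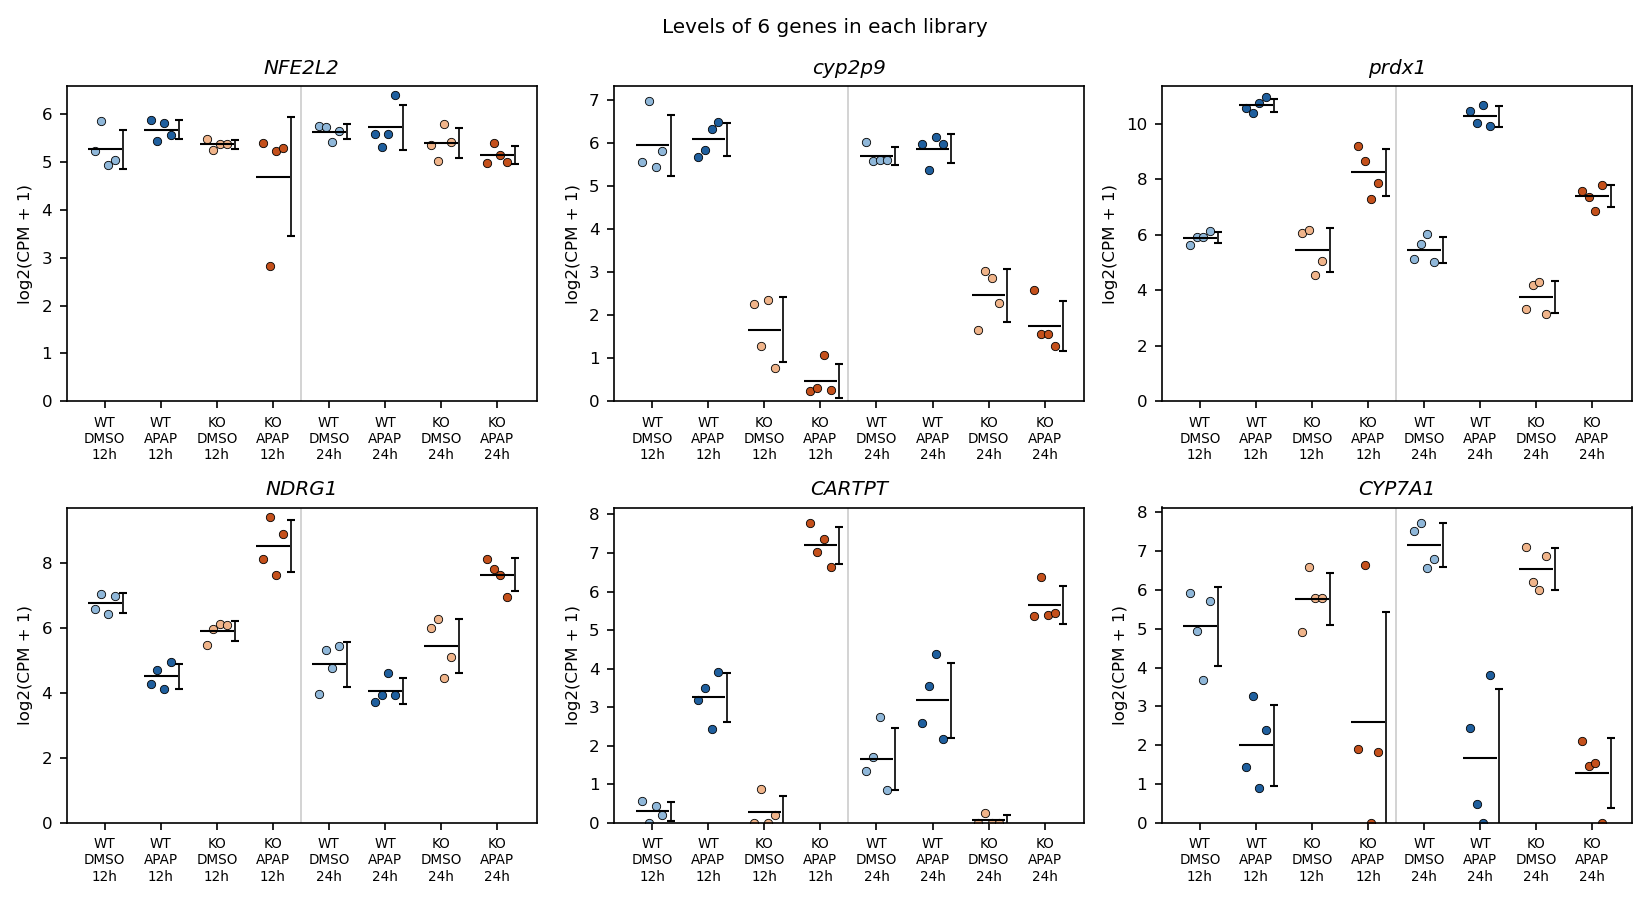
Expression as log2(CPM + 1) of NFE2L2, cyp2p9, prdx1, NDRG1, CARTPT and CYP7A1 in each library by group; points are libraries, the line is the mean and the bar the SD. Under APAP prdx1 had 1639 and 1259 CPM in WT and 344 and 172 CPM in KO at 12 h and 24 h.

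Whether the APAP response itself differs between KO and WT was tested directly. At 12 h NDRG1 (difference 5.05 ± 0.57) and agt (2.50 ± 0.39) responded more in KO, with a largest adjusted p of 0.000407. NDRG1 fell in WT, from 109 ± 22.8 to 22.3 ± 6.20 CPM (SD, n = 4), and rose in KO, from 59.7 ± 11.5 to 405 ± 216. Of the Nrf2 targets, 1 responded less in KO (adjusted over the list alone, 8). The full list had a median difference in log2 fold change of -0.82 (adjusted p = 2.06e-05, and adjusted p = 0.126 with an estimated correlation). Pancreas markers responded more and intestine markers less as sets, with medians of 0.40 and -1.14 (adjusted p = 0.0187 and 0.0113, and 0.764 and 0.650 with an estimated correlation), and these calls ended in 7 and 6 of 16 fits without 1 library. In all, 8 genes were called, 3 with a higher and 5 with a lower response in KO. The split turned to 30 higher and 22 lower without the filter and to 2 and 1 with only these groups in the fit, and was even with the replicate block (3 and 3). The count was 55 with DESeq2, 52 without the filter and 3 with only these groups in the fit. It was 5 and 3 without KO APAP 12 h replicate 1 or 4, 4 and 5 without KO DMSO 12 h replicate 1 or 2, 4, 3 and 4 without WT APAP 12 h replicate 1, 2 or 3, and 5 and 4 without WT DMSO 12 h replicate 1 or 3.

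At 24 h NDRG2 (ENSDARG00000011170) (-2.37 ± 0.42) and CMBL (ENSDARG00000073786) (-3.38 ± 0.65) responded less in KO, and CARTPT, which had 1 count in KO DMSO livers, NDRG1 (3.02 ± 0.56), COG2 (ENSDARG00000004037) (2.49 ± 0.46) and the ribosomal protein gene rps27l (ENSDARG00000100513), a p53 target (2.33 ± 0.42), responded more, with a largest adjusted p of 0.00754. Of the Nrf2 targets, 2 responded less in KO (adjusted over the list alone, 6). The median difference in log2 fold change of the list was -0.53 (adjusted p = 2.12e-06, and adjusted p = 0.0463 with an estimated correlation). Cell cycle genes responded less in KO as a set, with a median difference in log2 fold change of -1.56 (adjusted p = 1.07e-14, and adjusted p = 0.0463 with an estimated correlation); 5 members were lower adjusted over the list alone. Ribosome biogenesis genes responded more as a set, with a median difference in log2 fold change of 0.62 (adjusted p = 7.33e-07, and adjusted p = 0.217 with an estimated correlation), and cholesterol synthesis genes less, with a median difference in log2 fold change of -1.21 (adjusted p = 3.27e-06, and adjusted p = 0.217 with an estimated correlation). Pancreas, intestine and skeletal muscle markers responded less as sets, with medians of -1.13, -0.54 and -0.66 (adjusted p = 0.000298, 0.00393 and 0.00199, and 0.590, 0.426 and 0.590 with an estimated correlation), and the pancreas call turned without WT APAP 24 h replicate 2 (0.970). In all, 12 genes were called, 7 with a higher and 5 with a lower response in KO. The split turned with DESeq2 (13 higher and 20 lower), limma voom (15 and 19), without the filter (16 and 20), without the 3 libraries with fewest genes (16 and 19) and with only these groups in the fit (12 and 13). The count was 33 with DESeq2, 35 without the 3 libraries with fewest genes, 34 with limma voom, 36 without the filter and 25 with only these groups in the fit.

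The change of the APAP response from 12 h to 24 h was tested within each genotype. In WT, 9 responded more at 24 h (adjusted over the list alone, 19) among the cell cycle genes. As a list, the tested members had a median difference in log2 fold change of 1.95 (adjusted p = 2.05e-27, and adjusted p = 0.00304 with an estimated correlation). The list's mean log2(CPM + 2) in WT went from 3.08 ± 0.281 (SD, n = 4) at 12 h to 1.86 ± 0.167 at 24 h under DMSO. Under APAP it went from 3.21 ± 0.202 to 3.03 ± 0.211, so this difference went mostly with the lower DMSO level. The list includes TTK (6.06 ± 1.08), CDK1 (5.63 ± 0.86), the spindle gene TPX2 (ENSDARG00000078654) (5.34 ± 0.92) and the importin gene KPNA2 (ENSDARG00000038066) (5.32 ± 0.80). cox7a1 had a lower response at 24 h (-2.63 ± 0.43), and the largest adjusted p of these 5 genes was 0.00345. Of the red blood cell markers, 1 responded less at 24 h (adjusted over the list alone, 6). The list's median difference in log2 fold change was -2.12 (adjusted p = 4.71e-11, and adjusted p = 0.0192 with an estimated correlation). Proteasome subunits responded more at 24 h as a set, with a median difference in log2 fold change of 0.58 (adjusted p = 2.39e-06, and adjusted p = 0.0237 with an estimated correlation). Their mean log2(CPM + 2) in WT hardly moved under APAP, from 5.13 ± 0.0702 (SD, n = 4) at 12 h to 5.19 ± 0.140 at 24 h. Under DMSO it went from 4.92 ± 0.0419 to 4.48 ± 0.0525, so the difference went mostly with the lower DMSO level. Pancreas markers responded less at 24 h as a set, with a median difference in log2 fold change of -0.34 (adjusted p = 5.14e-06, and adjusted p = 0.423 with an estimated correlation). Their mean log2(CPM + 2) in WT went from 8.25 ± 0.949 to 9.57 ± 0.462 under DMSO and from 8.75 ± 0.258 to 8.91 ± 1.58 under APAP. In all, 26 genes were called, 16 with a higher and 10 with a lower response at 24 h. The split turned without the filter (31 higher and 33 lower) and without the 3 libraries with fewest genes (38 and 41). The count was 63 with DESeq2, 79 without the 3 libraries with fewest genes, 75 with limma voom, 64 without the filter and 16 with the replicate block. It was 15, 14 and 16 without WT APAP 12 h replicate 1, 2 or 4, 11, 9 and 12 without WT APAP 24 h replicate 1, 2 or 3, 17, 12 and 14 without WT DMSO 12 h replicate 1, 3 or 4, and 8 and 16 without WT DMSO 24 h replicate 1 or 3.

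In KO, the complement gene c8b (-3.47 ± 0.65) and the growth arrest gene GADD45B (-3.38 ± 0.64) had a lower response at 24 h than at 12 h, with adjusted p = 0.0110 and 0.0110; the call of GADD45B ended with the pancreas marker level as a covariate. Cell cycle genes responded more at 24 h as a set, with a median difference in log2 fold change of 1.16 (adjusted p = 8.53e-07, and adjusted p = 0.189 with an estimated correlation), 10 members being higher adjusted over the list alone. Their mean log2(CPM + 2) in KO went from 3.10 to 2.08 under DMSO and from 2.58 to 2.43 under APAP. Pancreas markers had a lower response as a set, with a median difference in log2 fold change of -1.94 (adjusted p = 2.83e-22, and adjusted p = 0.189 with an estimated correlation), 15 members being lower adjusted over the list alone. Their mean log2(CPM + 2) in KO went from 8.04 ± 0.857 (SD, n = 4) to 9.81 ± 0.605 under DMSO. Under APAP it went from 8.68 ± 0.639 to 8.58 ± 0.237, so this difference went mostly with the higher DMSO level. In all, 22 genes were called, 5 with a higher and 17 with a lower response. The split turned to 60 higher and 48 lower with DESeq2. The count was 108 with DESeq2, 49 without the 3 libraries with fewest genes, 121 with limma voom, 133 without the filter, 36 with robust edgeR and 14 with the pancreas covariate. It was 35 and 34 without KO APAP 12 h replicate 1 or 2, 6, 12 and 10 without KO APAP 24 h replicate 1, 2 or 3, 9 and 9 without KO DMSO 12 h replicate 1 or 2, and 9 and 5 without KO DMSO 24 h replicate 3 or 4.

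**Figure D4:**
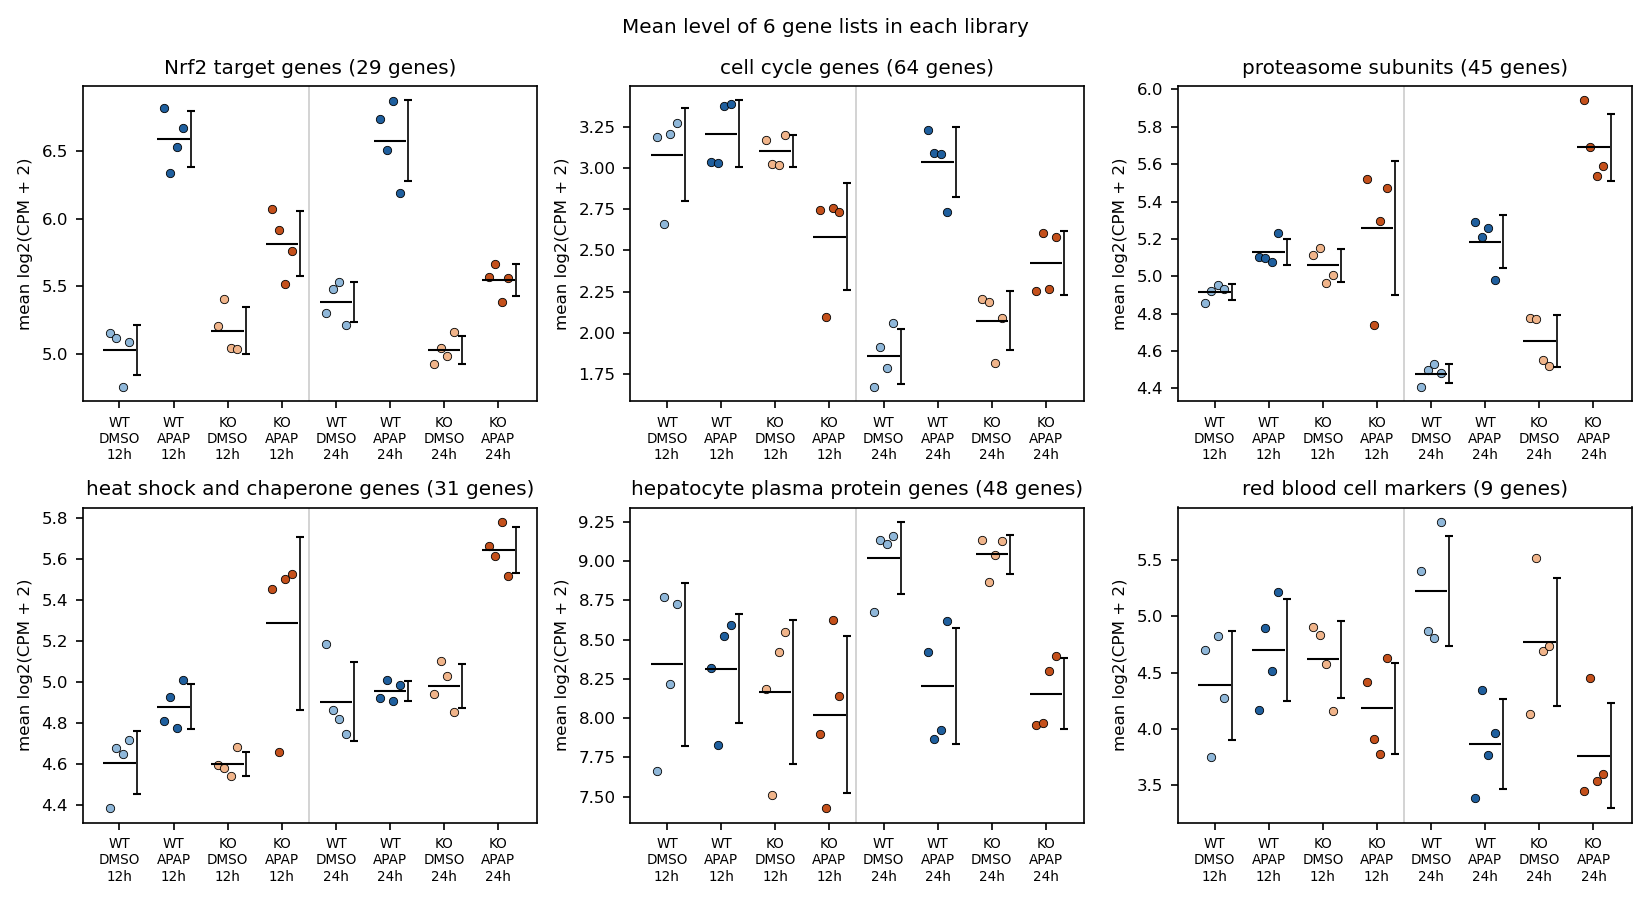
Mean log2(CPM + 2) of 6 gene lists (Nrf2 targets, 29 genes; cell cycle, 64; proteasome subunits, 45; heat shock and chaperones, 31; plasma proteins, 48; red blood cell markers, 9) in each library by group; points are libraries, the line is the mean and the bar the SD. The cell cycle mean in WT is 3.08 at 12 h and 1.86 at 24 h under DMSO, and 3.21 and 3.03 under APAP.

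The remaining lists include markers of other cells and tissues. Biliary markers were higher under APAP in KO at 24 h (19 tested, 4 rose (adjusted over the list alone, 4)). Over all tested members the median log2 fold change was 0.18 (adjusted p = 0.0245, and adjusted p = 0.261 with an estimated correlation). Intestine markers were lower there (22 tested, 2 fell (adjusted over the list alone, 2)), with a median log2 fold change of -0.69 (adjusted p = 0.0499, and adjusted p = 0.509 with an estimated correlation), a call that ended without KO APAP 24 h replicate 1 (0.0911) or 4 (0.102), or KO DMSO 24 h replicate 2 (0.129) or 3 (0.0603). Epidermis markers were lower there too (17 tested, 2 fell (adjusted over the list alone, 3)), with a median log2 fold change of -0.45 (adjusted p = 0.0252, and adjusted p = 0.417 with an estimated correlation), a call that ended without KO APAP 24 h replicate 1 (0.0584) and with the pancreas covariate (0.0986). Other lists passed in none of the 12 comparisons with the preset correlation: the smallest adjusted p was 0.197 for endoplasmic reticulum stress genes, 0.112 for fatty acid synthesis genes, 0.0581 for endothelial markers, 0.0915 for stellate and mesenchymal markers and 0.218 for macrophage markers. Neutrophil markers, with 4 tested members, were too few for the test; their mean log2(CPM + 2) in WT at 24 h was 3.22 ± 0.326 (SD, n = 4) under DMSO and 2.86 ± 0.294 under APAP, and in KO 2.69 ± 0.418 and 2.53 ± 0.185.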

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

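The counts of splits, the tests on named chromosomes other than 9, on 1 sign at both times, on the cell cycle list and with the pancreas marker level as a covariate were chosen only after the results were seen; the test of the share on chromosome 9 and that of other-tissue lists with camera were planned.

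Several libraries stood apart from the other 3 of their group. Of 375 groups tested, 37 had an outlying library, and about 1 in 20 is the share that chance gives. KO APAP 12 h replicate 2 was outlying in 8 of them. It had 4129 genes with a count (others 11340 to 12192), and its list means (log2) were 3.34 for endoplasmic reticulum stress genes (4.47 to 4.57), 4.66 for heat shock and chaperone genes (5.45 to 5.53), 2.84 for p53 pathway genes (3.81 to 3.94), 2.1 for cell cycle genes (2.73 to 2.76) and 3.16 for autophagy genes (4.23 to 4.32). It also had 6.10 CPM of NFE2L2 (36.7 to 41.2) and 99.3 CPM of CYP7A1 (0 to 2.75). The total count of WT APAP 12 h replicate 2 was 3971570 (4988820 to 5188130).

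Among shares of counts, red blood cell markers took 0.242% in KO DMSO 24 h replicate 2 (0.106% to 0.119%). Pancreas markers took 3.49% in KO APAP 24 h replicate 1 (4.29% to 4.40%) and 7.93% in KO DMSO 12 h replicate 3 (1.82% to 2.64%). Intestine markers took 1.1% in KO DMSO 24 h replicate 2 (0.762% to 0.802%) and 1.05% in WT APAP 24 h replicate 3 (0.508% to 0.552%).

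Among list means (log2), WT DMSO 12 h replicate 2 stood apart for cell cycle genes at 2.66 (3.18 to 3.27) and cholesterol synthesis genes at 4.44 (3.47 to 3.60), and replicate 3 for Nrf2 targets at 4.75 (5.09 to 5.15). WT DMSO 24 h replicate 1 had 8.68 for plasma protein genes (9.11 to 9.16), and WT APAP 12 h replicate 2 had 4.44 for fatty acid oxidation genes (4.64 to 4.69). WT APAP 24 h replicate 1 had 5.67 for glucose metabolism genes (5.58 to 5.60), 1.94 for macrophage markers (2.17 to 2.19) and 3.73 for epidermis markers (4.48 to 4.63), and replicate 3 had 4.48 for endoplasmic reticulum stress genes (4.17 to 4.21). KO DMSO 12 h replicate 2 had 5.03 for amino acid catabolism genes (5.62 to 5.7). KO DMSO 24 h replicate 3 had 10.71 for pancreas markers (9.43 to 9.62), and replicate 4 had 2.07 for neutrophil markers (2.87 to 2.96). KO APAP 24 h replicate 1 had 4.31 for acute phase and inflammation genes (3.43 to 3.57), replicate 2 had 4.45 for red blood cell markers (3.45 to 3.60) and replicate 3 had 4.76 for biliary markers (4.95 to 4.96).

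Among genes, cyp2p9 stood at 125 CPM in WT DMSO 12 h replicate 2 (42.6 to 55), 64.1 in WT DMSO 24 h replicate 1 (46.7 to 47.4), 1.09 in KO APAP 12 h replicate 3 (0.183 to 0.244) and 5.02 in KO APAP 24 h replicate 1 (1.42 to 1.97). nfe2l2b stood at 7.11 CPM in KO DMSO 24 h replicate 4 (1.3 to 1.80). In KO APAP 24 h replicate 2, CDK1 stood at 11.6 CPM (5.22 to 5.67) and CARTPT at 81.8 (40 to 42.5).

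The APAP response differed between KO and WT for 8 genes at 12 h and 12 genes at 24 h. At 12 h the differences were 5.05 for NDRG1 and 2.50 for agt, each called in all 16 fits without 1 library. HSPA5 (ENSDARG00000103846) (2.14), PIR (-5.85), gstt1b (-2.57) and cyp2n13 (-2.64) lost their call in 11, 9, 12 and 12 of these fits, with adjusted p up to 0.213, 0.142, 0.152 and 0.213, and NIPAL4 (-5.46) without KO APAP 12 h replicate 4 (0.0840) or WT APAP 12 h replicate 2 (0.0641). With only the compared groups in the fit these 5 calls ended as well (0.0643, 0.229, 0.150, 0.323 and 0.132), and with limma voom those of HSPA5 (0.0728), PIR (0.0633) and NIPAL4 (0.223), which rests on 1 count in KO APAP 12 h. The call of HSPA5 also ended with relative log expression (0.0626) and without the 3 libraries with fewest genes (0.150), and those of gstt1b (0.0694) and cyp2n13 (0.0705) with the replicate block. At 24 h the difference was 7.39 for CARTPT, a value that rests on 1 count in KO DMSO 24 h (ratio in KO 872, 95% counting interval 156 to 34469). The other differences were 3.02 for NDRG1, 2.49 for COG2, -2.37 for NDRG2, -3.38 for CMBL and -6.88 for ptgr1.2, whose call ended with robust edgeR (0.0704) and limma voom (0.108). atf5b (3.95), tm6sf2a (ENSDARG00000105208) (3.04) and gstp1.2 (-2.31) lost their call in 8, 14 and 9 of 16 fits, with adjusted p up to 0.109, 0.247 and 0.137, and gstp1.2 also with only the compared groups (0.0653). As lists called by both camera tests, Nrf2 targets (median -0.53) and cell cycle genes (-1.56) responded less in KO at 24 h.

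The response differed between 24 h and 12 h for 26 genes in WT and 22 in KO. In WT the differences were 5.63 for CDK1, 5.34 for TPX2, 5.32 for KPNA2 and -2.63 for cox7a1. cyp2n13 (-2.75) lost its call without WT APAP 24 h replicate 2 (0.0735) or WT DMSO 12 h replicate 3 (0.0795) or 4 (0.0650), and th2 (ENSDARG00000038384) (-6.66) in 12 of 16 fits, with adjusted p up to 0.195, with relative log expression (0.0540), the replicate block (0.0814), the pancreas covariate (0.123), only the compared groups (0.1003) and limma voom (0.405); th2 had no counts in WT DMSO 12 h. The lists that differed by both camera tests were proteasome subunits (0.58), cell cycle genes (1.95) and red blood cell markers (-2.12). In KO the differences were -3.47 for c8b and -3.38 for GADD45B, whose call ended with the pancreas covariate (0.0524). UBE2C (ENSDARG00000114670) (4.12) lost its call without KO DMSO 24 h replicate 4 (0.0585), KPNA2 (3.75) without KO APAP 24 h replicate 1 (0.0563) or KO DMSO 24 h replicate 3 (0.0642) or 4 (0.0585), and NIPAL4 (4.71) and adamts13 (ENSDARG00000076270) (-4.43) in 10 and 8 of 16 fits, with adjusted p up to 0.147 and 0.0965. With only the compared groups in the fit these 4 calls ended as well (0.123, 0.141, 0.0922 and 0.168), and with limma voom those of NIPAL4 (0.179) and adamts13 (0.0777). Both ended with the pancreas covariate too (0.0759 and 0.0524), and NIPAL4 without the 3 libraries with fewest genes (0.0617).

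Other splits of the samples were counted for each comparison. For APAP against DMSO, 1 of 35 splits, the real one, gave as many genes in WT at 12 h (205, highest other 1), WT at 24 h (364, highest other 13), KO at 12 h (594, highest other 41) and KO at 24 h (575, highest other 0). The same held, 1 of 35 each, for KO against WT under DMSO at 12 h (28, highest other 2) and 24 h (32, highest other 0) and under APAP at 12 h (254, highest other 10) and 24 h (136, highest other 3). The share of 1 of 35 is the smallest these splits can give, and no other split came near the real count. This argues against chance for these 8 counts. For the difference between KO and WT responses, 4 of 100 splits, the real one among them, gave as many at 12 h (8, highest other 41) and 3 of 100 at 24 h (12, highest other 39). For 24 h against 12 h it was 4 of 100 in WT (26, highest other 129) and 3 of 100 in KO (22, highest other 187), the real one again among them. These shares lie a little under 5%, a bound set after the results were seen, and random splits gave higher counts. Chance is thus not excluded for these 4 counts. In each of these 4 the highest other split called several times the real count. The genotype or time labels were shuffled within each treatment separately, so a split can carry a difference between genotypes or times into the contrast. These splits therefore cannot decide on chance for these 4 counts.

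The first pattern weighed is the set of genes that differ between KO and WT under DMSO. Linkage, alleles carried along with the mutation, was tested by chromosome in RefSeq names of GRCz12tu. Of the placed genes called at both times 14.3%, which is 1 gene of 7, lie on chromosome 9 with nfe2l2a, against 3.4% of other genes (Fisher's exact p = 0.216). Only 7 of the 10 genes could be placed, which leaves that test open. Of the 39 placed genes called at either time, 2.56% lie on it, against 3.41% of other genes. For the 6 genes called at both times and placed on other chromosomes, linkage to that locus is excluded, if nfe2l2a is the mutated copy. Of the 50 genes called at either time, 46 had the same sign at both times, which a difference between the fish lines elsewhere in the genome predicts and loss of Nrf2 predicts as well. These may be either, and they cannot be told apart in this design, where the genotype and the line go together.

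The second pattern is the weaker response of cell cycle genes to APAP in KO at 24 h. If it came from a higher level in KO livers under DMSO alone, KO and WT would share 1 level under APAP; the median between them under APAP was -0.98, with adjusted p = 5.12e-08, but adjusted p = 0.172 with an estimated correlation, so a share of the baseline cannot be told apart. Pancreas tissue as the whole source is argued against, since with the pancreas marker level as a covariate the list kept its call. The adjusted p with an estimated correlation was 0.0359, and 0.0463 without the covariate. Both lie near the threshold, and calls with an estimated correlation were not repeated without single libraries. Intestine and muscle marker levels were not used as covariates, so these tissues stay open. From 12 h to 24 h the list's mean log2(CPM + 2) did not rise under APAP, with 3.21 and 3.03 in WT and 2.58 and 2.43 in KO. Under DMSO it fell, from 3.08 to 1.86 in WT and from 3.10 to 2.08 in KO. At 12 h it was already lower in KO under APAP (2.58 ± 0.323, SD, n = 4) than under DMSO (3.10 ± 0.0954). Whether livers without Nrf2 divide less under APAP was not tested.

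The third pattern is the set of genes changed by APAP, set against other tissue in the dissected livers. With the pancreas marker level as a covariate, 194 of the 205 calls were kept in WT at 12 h, 300 of 364 in WT at 24 h, and 449 of 575 (78.1%, the lowest share) in KO at 24 h. The pancreas list passed in none of these fits (adjusted p = 0.904, 0.909 and 0.763 by camera), but the covariate is made of its genes, so this is no separate support. The kept calls argue against pancreas tissue as the whole source there, and a share of it stays open for the calls that ended. In KO at 12 h 83.0% were kept (493 of 594), but the pancreas list still passed with the covariate (adjusted p = 0.0188, and 0.302 with an estimated correlation), so pancreas tissue cannot be told apart for these genes. For other tissue at large, the bound set beforehand, that no pancreas, intestine, muscle or skin list passes camera, was not met: 10 of 16 such tests passed with the preset correlation and none with an estimated one, where the smallest adjusted p was 0.261. Other tissue as part of the source cannot be told apart from a change in the liver, since its calls depend on the test. Injury of hepatocytes by APAP, which the design names, is a candidate explanation that stays open.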

How the results depend on the processing

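The fit without the 3 libraries with fewest genes, robust edgeR, limma voom with quality weights and the pancreas covariate were chosen after seeing the data. Of 368 called results of named genes, 214 kept their direction and call in every setting they have a value in. Of 126 called gene lists 24 did, in both other list tests, the replicate block, the fit without 3 libraries, the pancreas covariate and fits without 1 library; lists were not tested in the other settings. All 368 kept their call with DESeq2 and 350 without the 3 libraries with fewest genes. With only the compared groups in the fit 291 kept it, 69 lost it and the rest had no value. Of the lists, 24 kept theirs with an estimated correlation and 46 with fry. Scaling by relative log expression moved the median of all genes by over 0.1 in 5 comparisons: from -0.07 to -0.18 for APAP in WT at 12 h, from -0.30 to -0.51 in KO at 12 h, from -0.30 to -0.45 for KO against WT under APAP at 12 h, and from 0.06 to 0.16 and 0.24 to 0.44 for 24 h against 12 h in WT and KO. Under it the calls split 244 higher and 345 lower for APAP in KO at 12 h (352 and 242 with TMM), 95 and 126 for KO against WT under APAP at 12 h (146 and 108), 12 and 21 under DMSO at 24 h (15 and 17) and 16 and 5 for 24 h against 12 h in WT (16 and 10). DESeq2 split those for APAP in WT into 210 and 198 at 12 h (154 and 51) and 324 and 339 at 24 h (187 and 177), and those for 24 h against 12 h in KO into 60 and 48 (5 and 17). Of the called lists 1 changed the sign of its median, xenobiotic metabolism for 24 h against 12 h in KO, from -0.14 to 0.06. With members without counts at their bound, list medians moved by at most 0.113. Whether the replicate numbers pair the libraries is not settled. Own-number correlations had a median of 0.0299, and 3 of 32 pairs were over 0.1. The own number correlated best in 14 of the 32 pairs, and for every APAP library against DMSO in KO at 24 h. The block was kept as an alternative. The simulated data, in which 4-fold changes were recovered at 30% and 16-fold changes at 60% in WT at 12 h, show what depth and spread limit. The pancreas list is left out of the counts for the pancreas covariate, which is made of its genes. Library composition was tested without 1 library only where its exact p was under 0.05.

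The order of the 12 counts below is APAP in WT at 12 h and 24 h and in KO at 12 h and 24 h, KO against WT under DMSO at 12 h and 24 h and under APAP at 12 h and 24 h, KO against WT responses at 12 h and 24 h, and 24 h against 12 h in WT and KO. DESeq2 gave 408, 663, 1258, 894, 104, 113, 761, 297, 55, 33, 63 and 108 in place of 205, 364, 594, 575, 28, 32, 254, 136, 8, 12, 26 and 22. Without the 3 libraries with fewest genes the counts were 414, 916, 595, 1215, 68, 171, 284, 443, 14, 35, 79 and 49, and with limma voom 389, 1030, 1004, 1633, 146, 428, 282, 569, 13, 34, 75 and 121. With only the compared groups in the fit they were 208, 777, 91, 1436, 13, 408, 32, 324, 3, 25, 32 and 27. Without the filter the counts were 74 and 75 for KO against WT under DMSO, 52 and 36 for the KO and WT responses, and 64 and 133 for 24 h against 12 h. The replicate block gave 16 for 24 h against 12 h in WT, and robust edgeR gave 36 and the pancreas covariate 14 for KO. In genes with a mean log2 CPM of at least 3 the correlation of responses was 0.599 and 0.723 between KO and WT at 12 h and 24 h, and 0.614 and 0.620 between the times in WT and KO (0.355, 0.437, 0.346 and 0.355 in all genes). The cause of these differences was not tested.

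Without 1 library the counts ranged from 139 to 167, 213 to 329, 351 to 650, 373 to 465, 12 to 23, 13 to 25, 101 to 273, 76 to 106, 3 to 10, 9 to 13, 8 to 32 and 5 to 35, in the same order. The libraries behind moves of over 1.5 times stand with each comparison. The agreement of responses was not run without single libraries. The pancreas marker list turned direction in WT at 24 h without WT APAP 24 h replicate 3 (adjusted p = 0.981, and 3.72e-11 at the other end of the range). It turned as well for the difference between KO and WT responses at 24 h without WT APAP 24 h replicate 2 (adjusted p = 0.970, and 1.56e-11 at the other end).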

Other observations

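All tests in this part were chosen after the results were seen, apart from the fit between KO and WT. Livers kept under DMSO were compared between 12 h and 24 h, which the design did not name. The mean log2(CPM + 2) of cell cycle genes, which drive division, went from 3.10 ± 0.0954 (SD, n = 4) to 2.08 ± 0.179 in KO (difference -1.03), and proteasome subunits from 4.92 ± 0.0419 to 4.48 ± 0.0525 in WT (-0.44) and from 5.06 ± 0.0878 to 4.65 ± 0.139 in KO (-0.40). Nrf2 targets went from 5.03 ± 0.183 to 5.38 ± 0.151 in WT (0.36), and plasma protein genes, products of mature hepatocytes, from 8.17 ± 0.462 to 9.04 ± 0.124 in KO (0.88). Under APAP the proteasome mean in KO went the other way than under DMSO, from 5.26 ± 0.359 to 5.69 ± 0.18 (0.43, and 0.26 without KO APAP 12 h replicate 2). Each of these 6 differences had an exact permutation p of 0.0286, the smallest possible, and none passed after adjustment over 20 such tests (0.0816). Nrf2 targets in KO under DMSO went the other way than in WT, from 5.17 ± 0.173 to 5.03 ± 0.103 (-0.14, exact permutation p = 0.2).

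In all, 6 genes were called between KO and WT in each of the 4 combinations of treatment and time, and cyp2p9 and zgc:171470 are the ones examined per library. cyp2p9, a cytochrome P450 gene, was at 40.2 to 125 CPM in the 16 WT libraries and 0.183 to 7.19 CPM in the 16 KO libraries. zgc:171470, chosen after its values were seen, was at 22.2 to 389 CPM in WT and 0 to 1.31 CPM in KO.

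A hypothesis was tested for the cell cycle genes that were higher under APAP in WT at 24 h: the difference could come from a fall under DMSO between 12 h and 24 h that APAP livers did not show. In WT DMSO livers the list's mean went from 3.08 ± 0.281 (SD, n = 4) to 1.86 ± 0.167, a difference of -1.22 (exact permutation p = 0.0286, adjusted p = 0.0816 over 20 tests). In WT APAP livers it went from 3.21 ± 0.202 to 3.03 ± 0.211, a difference of -0.17 (exact permutation p = 0.286). The values are consistent with this hypothesis: the division genes may have stayed at their 12 h level under APAP while they dropped under DMSO. Whether a delay of growth or renewed division keeps them high was not tested.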
